A study of Mus musculus with 6 samples.

How the data were processed

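RNA of 6 samples was measured on Illumina bead arrays: naive CD4+ T cells (day 0) and Th17 cells at days 2, 4, 7, 12 and 18 after activation with TRP-1 peptide, 1 sample each. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column with DNase treatment and labelled with biotin. The labels name a MouseRef-8 protocol, while the table holds 45281 probes, and the array design was taken only from the table. The deposited table gives for each probe an intensity per array, exported from GenomeStudio without normalization per the file headers, and a detection p-value per the file headers. How the detection p-value was computed is not given in the sources used here. The authors also deposited a table of normalized intensity values. Set against the signals, these deposited intensities keep each array's rank order (Spearman 1.0), share their quantiles across arrays to within 0.1, have a median of 3.1 in each column and fall to -12.4, from which a linear scale, background subtraction and quantile normalization were inferred; the method is not given in the sources used here. No batch, slide or scan information was used. No sort or gate is named in the labels. No per-sample column was left unused, and 18 were used.

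Signals were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, which fits normexp from the detection p-values, adds an offset of 16 and takes log2. Deposited intensities were put on the log2 scale after adding 16, as an alternative. Further computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Median signals before correction were 87.2 to 93.4, and detected probes 30.2% to 31.5% per array at a detection p below 0.01. Probe names were matched to gene symbols of the RefSeq annotation of GRCm38, used for names only: of 30854 names, 16223 matched a symbol and 5679 a synonym of a single gene, 8919 kept the file's name and 33 were numbers or altered by a spreadsheet, giving 28902 genes. Names can be old. Each gene was represented by its probe with the highest mean, and counted as detected where that probe was.

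A gene was called higher or lower between libraries where the brighter library detected it and the ratio was at least 2-fold. Where the dimmer library did not detect it, the lowest normalized signal of any detected probe on that array, or the probe's own if higher, was used, and the fold is a lower bound. With 1 library per time point no model was fitted. For each of 40 gene lists fixed before the data were examined, the median log2 difference of members detected in at least 1 library was placed among 10000 random lists of the same size matched in 20 bins of mean expression. Genes named in the text followed a rule fixed at the same time: the 5 with the largest differences each way at each activated day against day 0, the 10 each way on every activated day and at day 18 against day 2, the 5 highest and 3 lowest of each activated day against the nearest other, the 4 members with the widest range in each list, and 31 key genes; gene models without a name were passed over, and some genes that the rule names are not reported here. As a yardstick, the SD of the disagreement between a pair of probes of 1 gene, both detected in all 6 libraries, was 0.241 to 0.435 log2 units over 2398 genes. It does not describe probes undetected in a library.

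For genes on every day, 100 sets of unchanged libraries were simulated, with noise by intensity bin from the difference between days 12 and 18. The counting was tested on simulated data for day 2 against day 0, with 200 genes changed and the same noise, which also holds real changes. The 200 were drawn from genes with a probe detected in all 6 libraries. The shares called therefore do not describe genes that go to or come from below detection. Of genes made 3-fold higher 91.2% of 34 were called, and of those made 3-fold lower 72.7% of 33. At 8-fold the shares were 100.0% of 33 and 81.8% of 33, and at 2-fold, the size rule itself, 35.3% and 36.4%. Of 13340 unchanged genes 7 were called. Alternatives fixed in advance were median scaling, scaling on reference genes, no background correction, an offset of 50, the deposited normalized values, a detection p below 0.05, only genes detected in all 6 libraries, the mean of a gene's probes, leaving out each day in turn and Spearman correlation. Scaling on T cell identity genes and day 18 against day 4 were added after the data were seen, as were the neutrophil and macrophage lists without normalization between arrays, and the share of a further myeloid list over the members that lay at least 2-fold above the day 18 detection limit at day 2.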

Results

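Gene expression was measured on Illumina bead arrays in CD4+ T cells of mice that lack RAG1 and carry a transgenic T cell receptor specific for TRP-1, a melanocyte protein. Naive cells were collected before activation (day 0), and Th17 cells, helper cells named for the interleukin 17 they make, at days 2, 4, 7, 12 and 18 after activation with the TRP-1 peptide. Each of the 6 time points had 1 library, so differences between days have no replicate check, standard error or p-value, and no trend over the days was tested. Between 13687 and 14258 of 45281 probes were detected per array. After gene names were matched, 11954 genes were detected in at least 1 library and 8224 in all 6. The number of arrays limits the precision. "Higher" and "lower" below mean a difference of at least 2-fold between libraries, and "at least" marks a bound where the dimmer library did not detect the gene.

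Rag1, the recombinase gene named in the strain, was not detected in any of the 6 libraries, with normalized log2 signals from 4.51 to 4.76. Its probe position relative to the deleted part is not given in the sources used here, so this does not check the strain. Across genes detected in at least 1 library, Pearson's r was 0.886 to 0.901 between day 0 and each activated day, against 0.971 to 0.979 between successive activated days and 0.896 between day 2 and day 18. Genes are not independent replicates, so these correlations only describe the libraries.

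The comparison of naive with activated cells asks which genes differed at all 5 activated days. A set of 234 genes was higher on every activated day than at day 0, a set that was not tested for a theme. Zbtb32, a transcriptional repressor induced in activated lymphocytes, was at least 43.7-fold higher on each of these days. Ctla4, an inhibitory receptor of activated T cells, was higher by 14.6-fold or more, Il2ra, the interleukin 2 receptor alpha chain, by 11.5-fold or more, and Cdkn1a, the cell cycle inhibitor p21, by 17.3-fold or more. Cish, a STAT5-induced cytokine signalling inhibitor, the stearoyl-CoA desaturase Scd1 and the co-stimulatory receptor Tnfrsf9 were also among the 10 with the largest smallest difference.

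In the other direction, 484 genes were lower on every activated day than at day 0, and most of the 10 with the largest smallest difference were genes of red cells and their precursors. The gene listed as ERAF, which encodes the alpha-haemoglobin stabilising protein, was at 13.35 on the log2 scale at day 0 and 294-fold lower at day 2. Car1, carbonic anhydrase of erythroid cells, was 173-fold lower at day 2, and Slc4a1, the red cell anion exchanger, at least 138-fold lower. Klf1, the erythroid transcription factor, was in the same set, as was Fcna, a ficolin of macrophages. The haemoglobin genes have near-identical copies that a probe cannot separate. The fixed list of erythroid and platelet genes had a median log2 difference of -3.13 (percentile 0, -3.02 with undetected members at their bound) at day 2 and -4.67 (percentile 0, -3.95 with undetected members at their bound) at day 18 against day 0, with 15 of 15 members lower at day 18. The day 0 library is the reference of all 5 comparisons that follow, and these transcripts are part of each.

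All 5 comparisons share the day 0 library. In 100 simulations of unchanged libraries, a mean of 0.06 genes was higher and 0.04 lower on every day. With each activated library in turn as the reference, 137 genes stood 2-fold apart from all 5 others at day 2, 29 at day 4, 34 at day 7, 4 at day 12 and 165 at day 18, against 718 at day 0. Independent lists of the 5 comparisons' sizes would share 0.037 higher and 0.064 lower genes. Part of the excess may come from the shared day 0 library, which cannot be split. With arrays scaled on reference genes in place of quantile normalization, the counts on every day were 150 higher and 661 lower. Over genes detected in all 6 libraries they were 195 higher and 161 lower. The surplus of lower genes therefore rests on genes undetected in at least 1 library.

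Scaling changed the balance of the comparisons with day 0. Against day 0, reference gene scaling moved the median of all detected genes to -0.29, -0.27, -0.21, -0.14 and -0.18 at days 2, 4, 7, 12 and 18, from -0.01, 0.00, -0.01, 0.02 and 0.03 with quantile normalization. Day 18 against day 2 moved from 0.01 to 0.13. Median scaling moved day 18 to 0.17 against day 0 and 0.11 against day 2. Under median scaling, 1017 genes were higher and 928 lower at day 18 than at day 0. The reference list had 2 of 13 higher and 0 lower at day 2, the glycolytic genes Gapdh (4.29-fold higher) and Pgk1 (6.87-fold higher). Scaling on the T cell identity list, an alternative chosen after the data were seen, moved the medians to -0.58, -1.06, -1.31, -1.05 and -0.95 at the 5 activated days, and day 18 against day 2 to -0.35. Against day 0, the T cell identity list had medians of 0.53, 1.0, 1.51, 1.3 and 1.36 at these days with quantile normalization. A smaller share of T cell RNA at day 0, beside the erythroid signals, cannot be told apart from a change within T cells. This limit holds for every comparison with day 0. Between activated days the same list had medians of 0.54 at day 4 against day 2 and 0.43 at day 7 against day 4. At day 18 against day 2 its median was 0.96 (percentile 100), with 7 of 14 higher and 1 lower. The limit therefore holds for these comparisons too. In the later steps the list moved little, by -0.08 at day 12 against day 7 and 0.07 at day 18 against day 12. Differences given here are relative to the quantile-normalized arrays. List medians and named genes were not rerun with T cell identity scaling. Some list medians were smaller than its shift of all genes, such as mitosis at day 7 against day 0 (1.06, all genes at -1.31). Their sign could turn under that scaling, which was not tested.

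**Figure D1:**
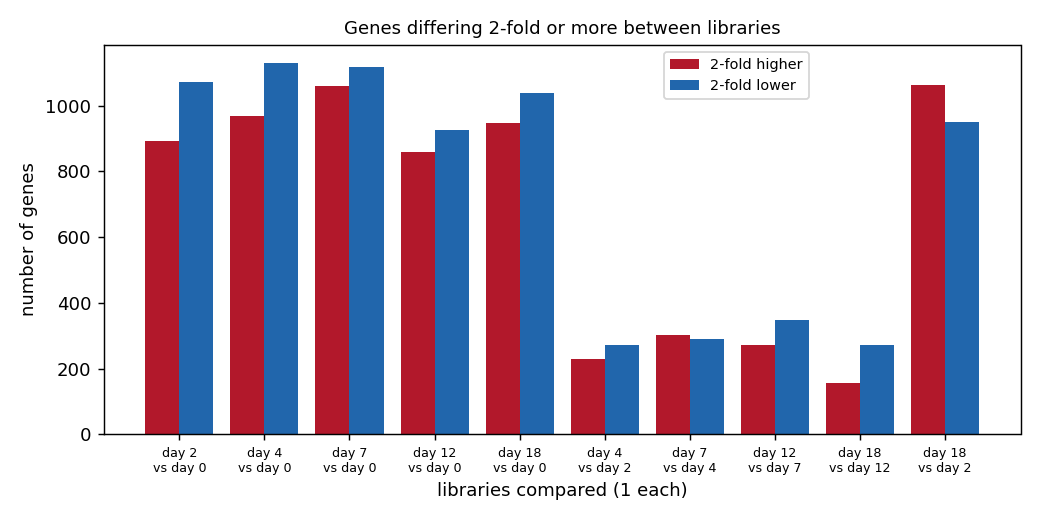
Number of genes (vertical axis) at least 2-fold higher or lower in the first library named than in the other, for each pair of libraries on the horizontal axis, 1 library each. Against day 0 the bars lie between 859 and 1129 genes, and between successive activated days between 157 and 347.

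**Figure D2:**
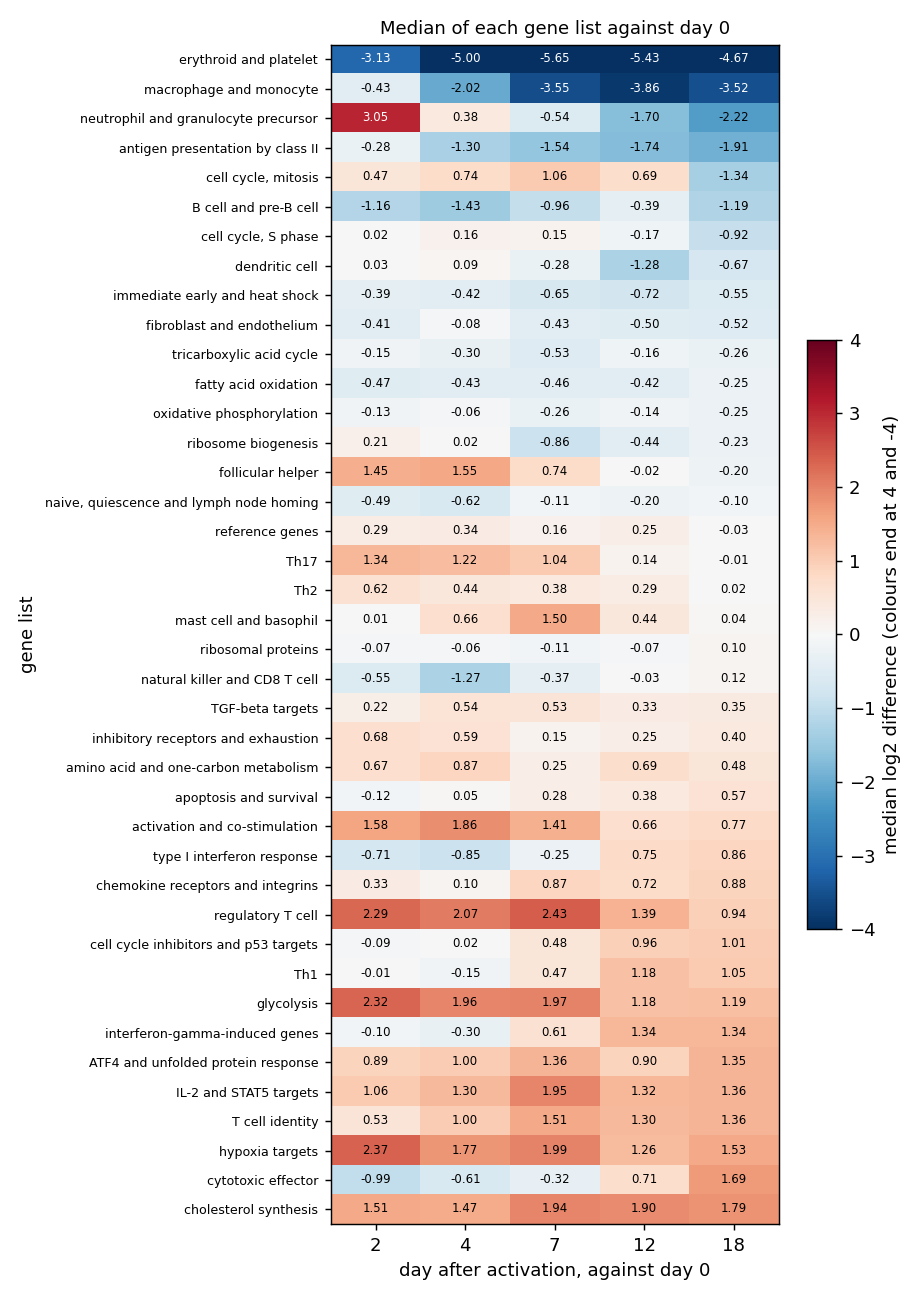
Median log2 difference against day 0 (colour and printed value) of the measured members of each of 40 gene lists (rows) at each activated day (columns), ordered by the value at day 18. The erythroid list lies lowest at day 18 (-4.67) and the cholesterol synthesis list highest (1.79).

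At day 2, the earliest day sampled after activation, Th17 and glycolysis genes were higher than at day 0. Il17f, an interleukin 17 cytokine, was at least 463-fold higher, and Il17a was at least 41.6-fold higher. In the fixed Th17 list 10 of 18 measured members were higher and none lower, with a median of 1.34 (percentile 100, 1.24 with undetected members at their bound); percentiles are among 10000 random lists matched on mean expression. Interleukin 2, the T cell growth factor encoded by Il2, was 46.5-fold higher, and Irf4, a transcription factor of T cell activation, at least 53.4-fold higher. The activation and co-stimulation list had 14 of 20 members higher, with a median of 1.58 (percentile 100).

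Some metabolic lists were higher at day 2 as well. Glycolysis genes had 13 of 16 higher and 1 lower, with a median of 2.32 (percentile 100, 2.11 with undetected members at their bound): the glucose transporter Slc2a1 was 14.2-fold higher and the phosphoglycerate mutase Pgam1 11.6-fold higher. Hypoxia targets had 9 of 12 members higher and a median of 2.37 (percentile 100), among them the prolyl hydroxylase Egln3, 33.9-fold higher. Cholesterol synthesis had 13 of 18 higher, with Cyp51 7.94-fold higher. Amino acid and one-carbon metabolism at 0.67 (percentile 99.9, 0.50 with undetected members at their bound) and the ATF4 and unfolded protein response list at 0.89 (percentile 100) had smaller medians. Other lists had no higher member: the medians were -0.13 (percentile 15.9) for oxidative phosphorylation, -0.15 (percentile 20.5) for the tricarboxylic acid cycle, -0.07 (percentile 38.7) for ribosomal proteins and -0.47 (percentile 1.73) for fatty acid oxidation, low among its random lists.

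Genes of naive cells and of other cell types moved at day 2 too. Klf2, a transcription factor of quiescent T cells, was 40-fold lower, although its list of naive and quiescence genes went both ways, with 4 of 20 higher and 6 lower. The immediate early gene Fos was 26.1-fold lower, in a list of immediate early and heat shock genes with 4 of 17 higher and 6 lower. Over the 12 members detected in all 6 libraries the median of that list turned to 0.46. Neutrophil genes had 9 of 13 higher and 3 lower than at day 0, with a median of 3.05 (percentile 100). S100a8, a calcium-binding protein abundant in neutrophils, was at 14.09, while Mpo, the neutrophil granule enzyme myeloperoxidase, was 6.43-fold lower. Arg1, arginase of myeloid cells, was at least 124-fold higher. The macrophage list had 3 of 18 higher and 7 lower. The haemoglobin genes Hba-a1 and Hbb-b1 were still at 13.27 and 13.67. In all, 893 genes were higher and 1072 lower. Reference gene scaling gave 560 higher and 1818 lower, and scaling on T cell identity genes 396 higher and 2926 lower.

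At day 4 Il17f, Il17a and Il21, a cytokine of Th17 and follicular helper cells, were at or near their highest values. Il17f was at least 482-fold higher than at day 0 and Il21 at least 10.3-fold higher. Il24, an interleukin 10 family cytokine on the fixed Th2 list, was at least 200-fold higher. Rora, a nuclear receptor of Th17 cells, was 5.65-fold higher. Il10, encoding interleukin 10, was at least 12.9-fold higher. The Th17 list had 8 of 18 higher and 1 lower, the Th2 list 4 of 13 higher and 1 lower and the follicular helper list 5 of 8 higher and 0 lower. Some lists share genes. Of those on the array, 7 of 10 follicular helper and 4 of 14 Th2 genes are also in another list. So are 7 of 16 IL-2 and STAT5 targets and 13 of 24 chemokine receptor and integrin genes, reported below. These lists therefore count some genes more than once. Over the 3 members detected in all 6 libraries the Th2 median turned to -0.56. The Th1 list had 2 of 16 higher and 4 lower, and type I interferon response genes 8 of 20 lower with a median of -0.85 (percentile 0.01).

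Other groups at day 4 against day 0 included Timp1, a metalloproteinase inhibitor, which was at least 133-fold higher, and Pdpn, podoplanin, at least 77.6-fold higher. IL-2 and STAT5 targets had 10 of 16 members higher. Mpo was at least 229-fold lower, and class II antigen presentation genes had 8 of 12 members lower, with a median of -1.30 (percentile 0, -1.15 with undetected members at their bound). T cell identity genes had 7 of 14 higher with a median of 1.0 (percentile 100). In all, 968 genes were higher and 1129 lower. Reference gene scaling gave 648 higher and 1818 lower, and scaling on T cell identity genes 273 higher and 6025 lower.

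By day 7 Il17f was still at least 219-fold higher than at day 0, and Il17a at least 18.1-fold higher, whereas Il22, a further Th17 cytokine, was no longer detected. Il24 was at least 65.9-fold higher. Ltb4r1, a leukotriene B4 receptor, was 47.5-fold higher, and Scd1 49.1-fold higher. The regulatory T cell list had 6 of 10 higher and 2 lower and a median of 2.43 (percentile 100). Of its 12 genes on the array, 5 are also in another list. Foxp3, the regulatory T cell factor, however lay at 8.68 against 9.51 at day 0. Of its 4 probes, 3 were detected in a library, at 5.0, 5.85 and 9.51 at day 0, so its level rests on the brightest. Mitosis genes had 12 of 22 members higher, with a median of 1.06 (percentile 100), whereas ribosome biogenesis genes had 6 of 19 lower, with a median of -0.86 (percentile 0), among them the RNA polymerase I subunit Polr1b, 2.44-fold lower.

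Markers of other cells at day 7 against day 0 went in different directions. Mast cell and basophil genes had 5 of 10 higher and 2 lower and a median of 1.5 (percentile 100, 0.99 with undetected members at their bound). Macrophage genes had 16 of 18 lower, and the haemoglobin gene Hba-a1 was 400-fold lower. T cell identity genes had 11 of 14 higher, with Cd28, the co-stimulatory receptor, 6.38-fold higher and Thy1 4.58-fold higher. In all, 1061 genes were higher and 1118 lower. Reference gene scaling gave 812 higher and 1597 lower, and scaling on T cell identity genes 231 higher and 7381 lower.

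At day 12 Il17f was at 6.08, and Il17a, Il21 and Ccr6, a Th17 chemokine receptor, were not detected. Gzmd, a granzyme, was at least 297-fold higher than at day 0, and Gzme at least 27.8-fold higher. Spp1, the secreted protein osteopontin, was at least 42.6-fold higher, Esm1 41.9-fold higher and Myl10, a myosin light chain, 45.4-fold higher. The cytotoxic effector list had 8 of 18 higher and 3 lower, the Th1 list 9 of 16 higher and 3 lower and interferon-gamma-induced genes 10 of 15 higher with a median of 1.34 (percentile 100). Cdkn2a, a cell cycle inhibitor locus linked to senescence, was at least 10.9-fold higher.

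Ifng itself, the interferon gamma gene, was at 7.65 at day 12, its lowest among the activated days, after 10.79 at day 2. The Th17 list at day 12 had a median of 0.14 (percentile 78.8). Macrophage genes were lower than at day 0 in 17 of 18 members and class II genes in 9 of 12, while dendritic cell genes had 1 of 9 higher and 3 lower, with a median that turned to 0.91 over the 3 members detected in all 6 libraries. Natural killer and CD8 T cell genes had 3 of 9 higher and 3 lower. In all, 859 genes were higher and 926 lower. Reference gene scaling gave 620 higher and 1230 lower, and scaling on T cell identity genes 175 higher and 6104 lower.

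Day 18 had the highest signals of the granzymes Gzmd, Gzme and Gzmg and the lowest median of the mitosis list. Gzmd was at least 906-fold higher than at day 0, Gzmg at least 290-fold higher and Gzme at least 270-fold higher, while Gzmb, the granzyme of most cytotoxic lymphocytes, was not detected in any library by its single probe. The Gzmd probe was at 14.70, near the array's highest value of 14.87, and rose by 1.61 log2 units from day 12 to day 18 against 2.89 on its dimmer probe, so its folds at day 18 rest on a level with little room above it. Prf1, the pore-forming protein perforin, was 13.4-fold higher, and Spp1 at least 237-fold higher. The cytotoxic effector list had 12 of 18 higher and 2 lower, with a median of 1.69 (percentile 100). The natural killer and CD8 T cell list had 3 of 9 higher and 3 lower. Within it, Cd8a and Cd8b1, the CD8 chains, were singled out after their values were seen: Cd8a was not detected in any library, and Cd8b1 was detected in all 6. Its brightest probe was at 10.26 at day 18, less than 2-fold from day 0, while its other probes were at 8.39 and 5.02 at day 0 and at 10.70 and 6.75 at day 18. These granzymes are near-identical paralogs, so a probe can bind more than 1 of their transcripts. Mitosis genes had 16 of 22 lower and a median of -1.34 (percentile 0), and S phase genes 11 of 28 lower.

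At day 18 against day 0, cell cycle inhibitors and p53 targets had 9 of 17 higher and 2 lower, with a median of 1.01 (percentile 100), and chemokine receptors and integrins 8 of 20 higher and 3 lower, with a median of 0.88 (percentile 100). Apoptosis and survival genes had 5 of 18 higher and 1 lower, with a median of 0.57 (percentile 99.8). TGF-beta targets had 3 of 10 higher and 0 lower, with a median of 0.35 (percentile 90.8), and inhibitory receptors 4 of 12 higher and 1 lower, with a median of 0.40 (percentile 96). B cell genes had 5 of 11 lower, and fibroblast and endothelial genes had 0 of 6 higher and 0 lower, with a median of -0.52 (percentile 12.3, 0.04 with undetected members at their bound). Cholesterol synthesis genes were above day 0 in 13 of 18 members. Hbb-b1 was at least 763-fold lower. In all, 948 genes were higher and 1039 lower. Reference gene scaling gave 577 higher and 1548 lower, and scaling on T cell identity genes 228 higher and 5297 lower.

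**Figure D3:**
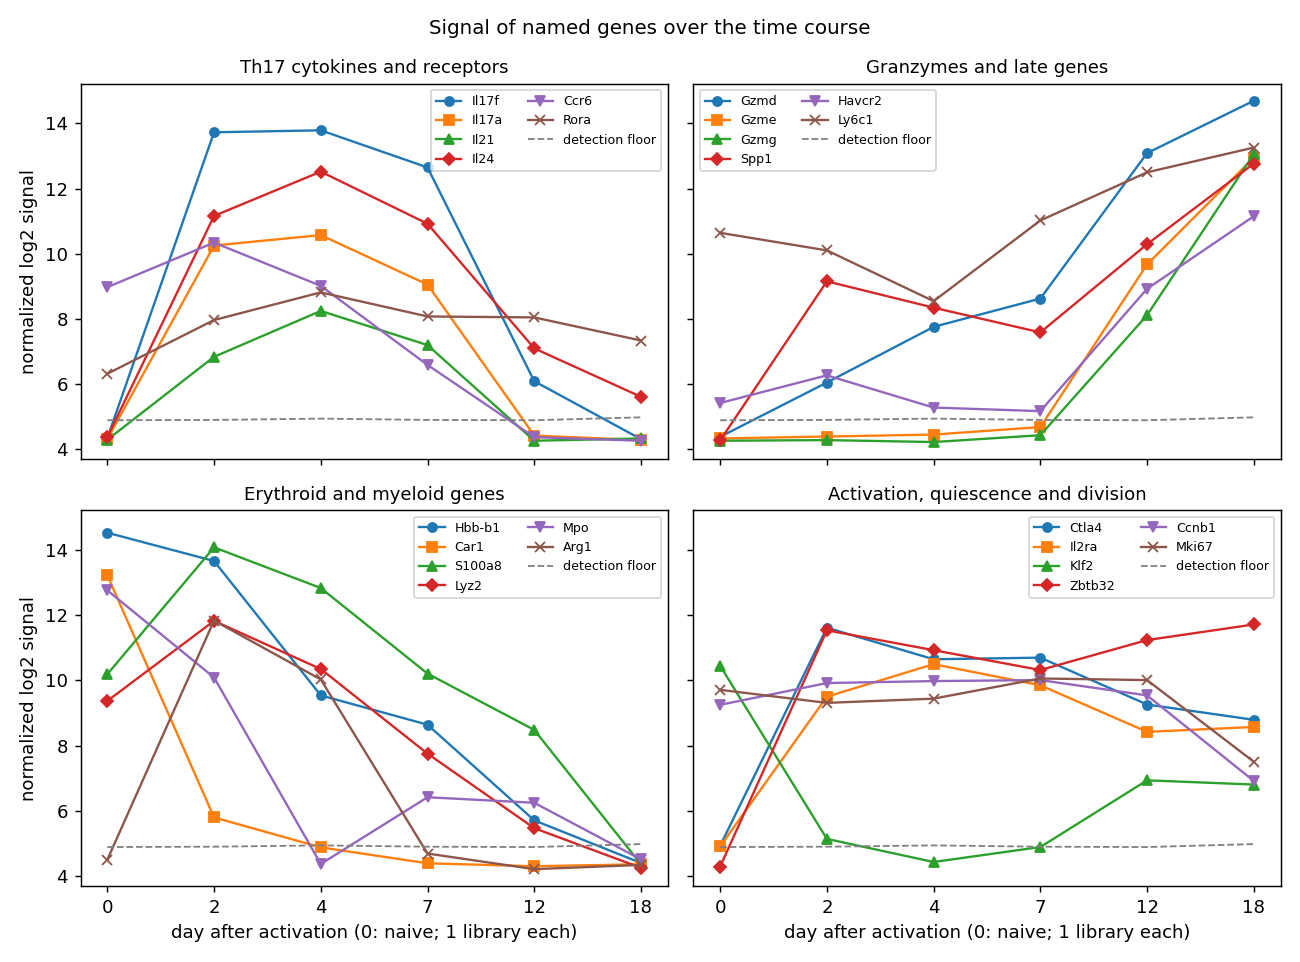
Normalized log2 signal (vertical axis) of named genes on each day after activation (horizontal axis, day 0 is naive; days are evenly spaced, not to scale), 1 library per point, with the dashed line at each array's lowest signal of a detected probe. Il17f lies between 12.65 and 13.79 from day 2 to day 7 and below the line at day 18, where Gzmd reaches 14.70.

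Among other genes fixed in advance, Il22 was detected only at days 2 and 4, at 5.78 and 5.52, and Csf2, encoding GM-CSF, was highest at day 2 (7.65 against 5.46 at day 0). Il23r, the interleukin 23 receptor, was not detected in any library by its 1 probe. Tnf, encoding tumour necrosis factor, was 11.4-fold higher at day 7 than at day 0, and Cd69, an early activation marker, 4.75-fold higher. Tbx21 and Gata3, the transcription factors of Th1 and Th2 cells, were lowest at day 7 (4.67, not detected) and day 4 (5.48). Il7r, the interleukin 7 receptor, was lowest at day 2 (8.50 against 10.11 at day 0), and Bcl2, a survival factor, was 3.9-fold higher at day 18. Pdcd1, encoding PD-1, stayed near the detection limit, at most 4.97.

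Successive activated days show when these groups changed places. From day 2 to day 4, 228 genes were higher and 272 lower: macrophage genes were lower in 15 of 18 members and neutrophil genes in 12 of 13, and Il3, a growth factor of myeloid cells made by T cells, was 13.1-fold lower, while Ltb4r1 was 10.5-fold higher. From day 4 to day 7, 303 were higher and 291 lower, or 438 higher and 256 lower under reference gene scaling. Interferon-gamma-induced genes were higher in 8 of 15 members and lower in 1, ribosome biogenesis genes were lower in 9 of 19, and Th17 genes had 2 of 18 higher and 5 lower, with a median that turned to 0.77 over the 7 members detected in all 6 libraries. Macrophage genes were again lower, in 10 of 18.

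From day 7 to day 12, 273 genes were higher and 347 lower. Il17f was 95.1-fold lower and Il17a at least 18-fold lower, in a Th17 list with 8 of 18 members lower and a median of -0.95 (percentile 0). Cytotoxic genes were higher in 8 of 18 and type I interferon response genes in 6 of 20, and Th1 genes had 6 of 16 higher and 2 lower. Mast cell genes were lower in 6 of 10. From day 12 to day 18, 157 were higher and 271 lower. Mitosis genes were lower in 20 of 22 members, with a median of -2.16 (percentile 0): Ccnb1, cyclin B1, was 6.18-fold lower and Mki67, the proliferation marker, 5.69-fold lower. Kif2c, a mitotic kinesin outside that list, was 5.9-fold lower. Gzmg was 30.8-fold higher and Gzmf at least 17-fold higher. Ctsg, cathepsin G of neutrophils, was 21.9-fold higher at day 18, while S100a8 was at least 11.4-fold lower.

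The last activated day against the earliest gives the full span after activation, 1064 genes higher and 950 lower at day 18 than at day 2. Gzmd was 404-fold higher on the same probe near the top of the array, Havcr2, the inhibitory receptor TIM-3, 29.7-fold higher, and Tnfrsf11b, osteoprotegerin, at least 34.5-fold higher. The cytotoxic effector list had 14 of 18 higher and 1 lower, with a median of 3.11 (percentile 100), type I interferon response genes 13 of 20 higher and Th1 genes 9 of 16 higher and 2 lower. The natural killer and CD8 T cell list had 3 of 9 higher and 0 lower, with a median of 0.41 (percentile 93.3). The higher members were Cd244a, a receptor of cytotoxic lymphocytes (6.9-fold higher), and, named after their values were seen, Eomes, a transcription factor of such cells (at least 3.57-fold higher), and Il2rb, an interleukin 2 receptor chain (2.47-fold higher). In the other direction Il17f was at least 434-fold lower, the Th17 list had 2 of 18 higher and 8 lower, and glycolysis had 10 of 16 members lower, hypoxia targets 6 of 12 and mitosis 19 of 22.

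Myeloid markers moved with this comparison. S100a8 was at least 557-fold lower at day 18, Lyz2, lysozyme of myeloid cells, at least 117-fold lower, and Il1b, interleukin 1 beta, at least 101-fold lower. Of the macrophage list 15 of 18 members were lower, the class II list had 1 of 12 higher and 7 lower, and the neutrophil list had 1 of 13 higher and 12 lower. The higher neutrophil member was Ctsg, 10.3-fold higher at day 18. With day 4 in place of day 2, a comparison added after the data were seen, 878 genes were higher and 799 lower at day 18. A further probe of the same gene went the same way in 97.0% of the 396 genes with a 2-fold difference and a pair of probes detected in all 6 libraries. S100a8 and Il1b, with 1 probe each, are not among them. The share does not describe falls to below detection.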

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

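No paired analysis was possible because each time point has 1 library. Scaling on T cell identity genes, day 18 against day 4 and no normalization between arrays were chosen after the data were seen; the other settings were fixed in advance. Counts of genes stayed within 1.5 times the main value under median scaling, the deposited normalized values, a detection p below 0.05 and the mean of probes (22 counts each). So did the 2 counts of day 18 against day 2 with day 4 in place of day 2, and the 2 counts on every activated day with each of these days left out in turn, the only counts run in these settings. Reference gene scaling gave 560 (main 893) higher at day 2 against day 0, 1818 (main 1072) lower at day 2 against day 0, 1818 (main 1129) lower at day 4 against day 0, 577 (main 948) higher at day 18 against day 0, 150 (main 234) higher on every activated day. The cause was not tested. No background correction gave 476 (main 893) higher at day 2 against day 0, 535 (main 1072) lower at day 2 against day 0, 515 (main 968) higher at day 4 against day 0, 597 (main 1129) lower at day 4 against day 0, 588 (main 1061) higher at day 7 against day 0, 585 (main 1118) lower at day 7 against day 0, 433 (main 859) higher at day 12 against day 0, 510 (main 926) lower at day 12 against day 0, 487 (main 948) higher at day 18 against day 0, 573 (main 1039) lower at day 18 against day 0, 92 (main 228) higher at day 4 against day 2, 106 (main 272) lower at day 4 against day 2, 132 (main 303) higher at day 7 against day 4, 133 (main 291) lower at day 7 against day 4, 107 (main 273) higher at day 12 against day 7, 149 (main 347) lower at day 12 against day 7, 62 (main 157) higher at day 18 against day 12, 136 (main 271) lower at day 18 against day 12, 583 (main 1064) higher at day 18 against day 2, 519 (main 950) lower at day 18 against day 2, 122 (main 234) higher on every activated day, 262 (main 484) lower on every activated day. Background left in the signal shrinks ratios by construction. An offset of 50 gave 640 (main 968) higher at day 4 against day 0, 135 (main 228) higher at day 4 against day 2, 152 (main 272) lower at day 4 against day 2, 187 (main 303) higher at day 7 against day 4, 187 (main 291) lower at day 7 against day 4, 156 (main 273) higher at day 12 against day 7, 220 (main 347) lower at day 12 against day 7, 86 (main 157) higher at day 18 against day 12. The larger offset shrinks ratios of dim genes by construction. Keeping only genes detected in all 6 libraries gave 654 (main 1072) lower at day 2 against day 0, 674 (main 1129) lower at day 4 against day 0, 637 (main 1118) lower at day 7 against day 0, 460 (main 926) lower at day 12 against day 0, 584 (main 1039) lower at day 18 against day 0, 149 (main 228) higher at day 4 against day 2, 104 (main 272) lower at day 4 against day 2, 147 (main 291) lower at day 7 against day 4, 176 (main 273) higher at day 12 against day 7, 186 (main 347) lower at day 12 against day 7, 87 (main 157) higher at day 18 against day 12, 622 (main 950) lower at day 18 against day 2, 161 (main 484) lower on every activated day. Fewer genes enter by construction. More genes were then higher than lower on every activated day (195) and at days 4, 7, 12 and 18 against day 0 (705, 813, 678 and 728). Scaling on T cell identity genes gave 396 (main 893) higher at day 2 against day 0, 2926 (main 1072) lower at day 2 against day 0, 273 (main 968) higher at day 4 against day 0, 6025 (main 1129) lower at day 4 against day 0, 231 (main 1061) higher at day 7 against day 0, 7381 (main 1118) lower at day 7 against day 0, 175 (main 859) higher at day 12 against day 0, 6104 (main 926) lower at day 12 against day 0, 228 (main 948) higher at day 18 against day 0, 5297 (main 1039) lower at day 18 against day 0. By construction this shifts every gene of an array alike. It was not run on lists or named genes. The lowest correlation across genes between successive activated days was 0.958 with Spearman and 0.97 with deposited values, and the highest of day 0 with an activated day 0.866 and 0.897. Of 400 list medians 2 changed sign under median scaling, 1 under reference gene scaling and 22 with only genes detected in all 6 libraries, counting medians in the outer tails of their random lists. The changed values were Th2 0.02 at day 18 against 12 under median scaling, oxidative phosphorylation 0.05 at day 18 against 0 under median scaling, chemokine receptors and integrins -0.03 at day 2 against 0 under reference gene scaling. The cause was not tested. Keeping only genes detected in all 6 libraries drops by construction members that went to or came from below detection, so these values describe only the members left. They were naive, quiescence and lymph node homing (15 members) 0.39 at day 4 against 0, Th17 (7 members) 0.77 at day 7 against 4, Th1 (10 members) -0.07 at day 7 against 4, Th2 (3 members) -0.96 at day 2 against 0, -0.56 at day 4 against 0, -0.47 at day 4 against 2, 0.64 at day 12 against 7, 0.36 at day 18 against 12, 0.54 at day 18 against 2, immediate early and heat shock (12 members) 0.46 at day 2 against 0 and 0.02 at day 4 against 0, dendritic cell (3 members) 0.91 at day 12 against 0 and 0.47 at day 7 against 4, neutrophil and granulocyte precursor (1 member, Ctsg) -1.42 at day 2 against 0, 1.94 at day 18 against 0, 0.41 at day 7 against 4, 0.41 at day 12 against 7, 4.45 at day 18 against 12, 3.37 at day 18 against 2, mast cell and basophil (7 members) -0.43 at day 12 against 0 and -0.07 at day 4 against 2, fibroblast and endothelium (1 member) 0.43 at day 7 against 4. Without normalization between arrays, the neutrophil and macrophage medians at day 18 against day 2 were -5.65 and -3.17. Of 418 differences of named genes against day 0 or of day 18 against day 2, none changed sign under 8 settings fixed in advance. All were 2-fold or more, many picked for size: a weak check. Only 181 had a value on genes detected in all 6 libraries, and 58 went below 2-fold without background correction. Sizes were less stable: 326 (326 toward 0) without background correction, 285 (285 toward 0) with an offset of 50, 80 (79 toward 0) with the mean of probes, 10 (8 toward 0) under median scaling and 9 (6 toward 0) under reference gene scaling moved by more than the probe yardstick. Of the 400 list medians, 167 (167 toward 0) without background correction, 159 (83 toward 0) under reference gene scaling, 139 (55 toward 0) with only genes detected in all 6 libraries, 136 (136 toward 0) with an offset of 50, 76 (34 toward 0) under median scaling, 47 (39 toward 0) with the mean of probes and 37 (2 toward 0) with the deposited values moved, without a change of sign among called ones, by more than 1 SD of their random lists. Signal over background limits dim genes: the lowest signal of a detected probe was 4.88 to 4.97 on the log2 scale.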

Other observations

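Tests of normalization, of the day 18 array, of shared granzyme probes and of myeloid genes able to fall were chosen after the results were seen; the 3 further marker lists were written after the patterns had been seen but before their own values were. Other genes moved as well. Saa3, an acute phase protein, was at 8.49 at day 4 and not detected at days 0, 12 and 18. Aqp3, a glycerol channel, was highest at day 4 (8.37), and Ecm1, extracellular matrix protein 1, at day 7 (12.77). Trat1, an adaptor of the T cell receptor, was highest at day 12 (10.03). Ly6c1, a surface antigen of memory T cells, was lowest at day 4 (8.54) and highest at day 18 (13.26), and Samd9l, an interferon-induced gene, had the same order (6.79 and 11.13). Fcer1g, a signalling chain shared by several receptors, was lowest at day 7 (8.56) and at 12.02 at day 18. Ighm, an immunoglobulin heavy chain gene, was at 10.11 at day 0, 6.44 at day 4 and 10.22 at day 18.

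Erythroid genes were highest in the day 0 library. Normalization and background correction do not account for this, since under the setting nearest to 0 the erythroid list median at day 18 against day 0 was still -2.78. A hypothesis is that the day 0 sample held red cell precursors. Of a further list of erythroid genes, 19 of 23 measured members (82.6%) were at least 2-fold higher at day 0 than on every activated day. This was past the 80% set beforehand, against 484 of all 11954 genes detected in at least 1 library. Members counted as measured if any library detected them. Some, such as Kel and Ermap, were below the detection limit on all activated days and could only be higher at day 0. The 80% was therefore met in part through the filter. The most abundant erythroid genes, Hbb-b1 and Hba-a1, were at 14.54 and 14.26 at day 0 but still at 13.67 and 13.27 at day 2, less than 2-fold lower, and so did not follow ERAF, 294-fold lower at day 2, or Car1, 173-fold lower; 0 of the 15 genes of the fixed list are in another list. A change within the T cells on activation was not tested and stays open, and the labels name no sort that would remove such cells.

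Neutrophil genes as a group were highest at day 2, and neutrophil and macrophage genes were lower on later days, with Ctsg at day 18 an exception. A weaker day 18 array does not account for this: without normalization between arrays, the 7625 genes bright enough at day 2 to fall 2-fold had a median difference of -0.43 at day 18, against -5.65 for the neutrophil and -3.17 for the macrophage list. That myeloid cells were fewer on later days may be a source: of a further myeloid list, 16 of 26 members (61.5%) were at least 2-fold higher at day 2 than at day 18, between the 80% and 50% set beforehand, but 7 lay too near the detection limit to show this, and of the other 19 it held for 16 (84.2%), past the 80%, against 12.8% of all genes that bright. Ncf4, a phagocyte oxidase subunit on that list singled out after its values were seen, was an exception, at 10.13 at day 2 and 10.96 at day 18. The neutrophil gene S100a8 was at 14.09 at day 2. A change within the T cells was not tested and stays open, and the labels name no sort that would remove such cells.

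The granzymes Gzmd, Gzme and Gzmg had their highest signals at days 12 and 18. So did the median of the cytotoxic effector list against day 0, at 0.71 and 1.69. At day 12, 8 of its 18 members were higher than at day 0 and 3 lower, and at day 18, 12 were higher and 2 lower. Gzmb was not detected in any library. Outgrowth of natural killer cells was weighed: of a further list of their genes, 1 of 11 measured members (9.1%) was higher at day 18 than at day 2 (Sh2d1b1, at 6.59 at day 18, named after its values were seen), under the 20% set beforehand, which argues against it, although the fixed list of natural killer and CD8 T cell genes had 3 of 9 higher and 0 lower, with a median of 0.41 (percentile 93.3). That Gzme and Gzmg report only 1 shared transcript is argued against by their changes from day 12 to day 18, which differed by 1.67 log2 units, beyond 0.92, which is 2 times the root mean square of the disagreement between probes of 1 gene over 68 genes that changed 2-fold or more over these days, of which 1 disagreed as much; the probes of Gzme disagreed by 0.36 and those of Gzmd by 1.28, the brighter of them at 14.70, near the array's highest value of 14.87, and partial cross-binding stays open. Outgrowth of CD8 T cells had no planned test and stays open, with Cd8a not detected in any library and Cd8b1 at 9.93 at day 2 and 10.26 at day 18 on its brightest probe, less than 2-fold apart, but at 8.94 and 10.70 and at 5.22 and 6.75 on its others. A late change within the activated cells is a hypothesis that was not tested on its own.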
